A study of Mus musculus with 12 samples.

How the data were processed

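Bone marrow HSCs of poly(I:C)-treated WT and RUNX1 KO mice were sorted by flow cytometry into CD41pos and CD41neg fractions, RNA was extracted with a Qiagen miRNeasy Micro kit, and libraries were made with the SMART-Seq v4 Ultra Low Input kit, per the labels' protocols. This kit copies full-length transcripts by template switching and does not mark the strand, so overlapping and antisense genes cannot be told apart. The tools named in the submitters' processing notes are FastQC 0.11.7, cutadapt 1.9.1, STAR 2.6.1e and featureCounts 1.6.2, with the mm10 genome build; their settings and the annotation release are not given in the sources used here. The authors deposited a table of gene counts, whole reads per gene with no normalization, and this table was the basis of every main test. The authors also deposited a TPM table of the same genes and libraries, which served only as an alternative unit. Over 4324 genes of at least 20 TPM, the ratio of counts to TPM within a gene deviated between libraries by at most 0.374% after scaling, so for these genes the tables differed by little more than a factor per gene and library. Among the gene names of the count table, 27 had been turned into dates, and their names were taken from the TPM table, which lists the same genes in the same order. Gene names are those of the files; 90.3% matched symbols of the RefSeq table of the same build. Coordinates are 1-based, from the GENCODE vM21 annotation of GRCm38 (mm10), and were used only to place named genes.

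Groups were taken from the labels: genotype and gate gave 4 groups of 3 libraries. Of 35869 genes, 19395 passed edgeR's filterByExpr on the 4 groups and were tested, and 16474 were left out. Counts were scaled by TMM, and all 12 libraries entered 1 quasi-likelihood fit of 4 group means (edgeR 4.0.16 in R 4.3.3), from which 5 comparisons were drawn: KO against WT in each gate, CD41pos against CD41neg in each genotype, and the interaction. A shared fit was used since 3 libraries against 3 estimate the spread poorly. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and all tests were two-sided. Log2 fold changes and their SE are those of the fitted model, with the SE derived from the F statistic. Gene lists (26 in all, 24 by members and 2 by name pattern, 558 entries of which 5 had no row and 1 was found under an older symbol) covered blood lineages, signalling, metabolism, cell cycle, ribosomes and markers of other cells of the marrow. They were tested with camera (limma 3.58.1, preset correlation 0.01, voom values) and adjusted over the 26 lists and 5 comparisons together, then again with an estimated correlation and with fry. The comparisons, the lists, the rule for named genes and the alternatives listed first below were fixed before the data were examined. Named genes were Runx1, Runx2, Runx3 and Itga2b. They were also the 8 highest and 8 lowest log2 fold changes among genes past the threshold with a mean of at least 10 CPM in the higher group. Of these all 3 libraries of a group had to lie above those of the other (not asked of the interaction), and predicted genes, pseudogenes, mitochondrial and sex-linked genes (Xist, Tsix and 4 Y-linked genes) were left out. Named as well were up to 4 members of each described list with the smallest adjusted p. A gene that this rule names is not reported here. Genes outside this rule are said to have been chosen after their values were seen, as were Nr4a1, Atf3, Gm29779 and Mocs1 for the libraries that stand apart.

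Alternatives were DESeq2 1.42.0, its size factors in edgeR, other low-count filters, fits of only the groups compared, the animal label or replicate number as a block, quality weights, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), a minimum log2 change of 1, and leaving out each library in turn. A block that pairs WT libraries by library number was planned too. A term for the 4 WT libraries numbered up to 6 and a Y-linked covariate were added after seeing the data. So were fits without or with only these 4 libraries and a blocked fit of the KO libraries alone. List tests with the animal label as a fixed block were added then as well. Pairing was checked by correlating deviations from group means over 10442 genes. Libraries of the same KO label correlated across gates (0.38, 0.54 and 0.41), so the KO numbers pair the samples, whereas the labels shared by WT libraries gave 0.03 and -0.52. Counts of replicate libraries differed by more than sampling noise in all 12 pairs (chi-square per degree of freedom 14.8 to 259), and none held identical values. Xist and Y-linked genes were read as a check of which libraries can share an animal.

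Before use, the tests were run on counts simulated from the overall mean of each gene and the real library sizes. Of 19395 genes 200 above a minimum mean level were changed, and 30 more formed a list changed by 1.5-fold. The simulation held neither the shift of the 4 WT libraries nor pairing as such. Its spread per gene was estimated from the real libraries within the 4 groups, so both entered as noise. The rates are therefore not those of data free of the shift or of pairing. Of genes changed by 1.5-, 2- and 4-fold the test recovered 10.4%, 41.8% and 80.3% for KO against WT in CD41pos cells, 5.97%, 40.3% and 74.2% in CD41neg cells, 5.97%, 38.8% and 78.8% for the gates of WT, 2.99%, 44.8% and 74.2% for the gates of KO, and 1.49%, 11.9% and 56.1% for the interaction. Between 0 and 3 unchanged genes were called in each. Depth was 44108035 to 58946457 counts per library, so 3 counts correspond to less than 0.1 CPM. Mitochondrial transcripts held 0.355% to 0.564% of the counts and the 50 most abundant genes 5.68% to 7.01%.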

Results

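RNA was sequenced from haematopoietic stem cells (HSCs) of mouse bone marrow, sorted by flow cytometry into CD41-positive (CD41pos) and CD41-negative (CD41neg) fractions. CD41 is the integrin alpha-IIb chain encoded by Itga2b, a surface protein of megakaryocytes, platelets and a part of the stem cells. All mice carried floxed Runx1, the gene of a transcription factor of blood formation, and those called knockout (KO) also carried the interferon-inducible MxCre1 driver, while the controls (WT) did not. Both genotypes received 4 injections of poly(I:C), a double-stranded RNA that induces interferon and so the recombinase, and were studied 4 weeks later. The design crossed genotype with gate, giving 4 groups of 3 libraries. Total gene counts ran from 44108035 to 58946457 per library, and between 21973 and 27097 genes had at least 1 count. Levels below are TMM-normalised counts scaled to library size (CPM) as mean ± SD with n = 3 libraries, and changes are log2 fold changes ± SE with adjusted p-values of edgeR's quasi-likelihood test. The labels do not state that every library came from a separate animal. The p-values thus measure the spread between these libraries, which may be partly technical. The KO libraries of both gates share animal labels, and deviations of same-label libraries from their group means correlated across gates (0.38, 0.54 and 0.41). The main fit did not pair them, so in the comparison of KO gates and the interaction paired libraries were treated as independent. Numbers of genes called with the animal label as a block are given below.

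Within WT, 4 of the 6 libraries (CD41pos WT 1 and 4, CD41neg WT 2 and 4, whose library numbers run up to 6) stood apart from WT 3 of each gate and from all 6 KO libraries. Nr4a1, an immediate early gene, measured 18.6 to 27.7 CPM in those 4 libraries and 237 to 396 CPM in the other 8, and Atf3, a stress-response transcription factor, measured 0.37 to 1.66 against 31.4 to 85.6 CPM. The unnamed gene Gm29779 went the other way, with 237 to 449 against 0.221 to 0.894 CPM. With a term for these 4 libraries in the model, 44 genes were higher and 78 lower in them at an adjusted p below 0.05. The term compares them with WT 3 of their gate, since no KO library is among them. Calls of the genes and lists reported below that this term ended or brought about are given beside them. The 4 libraries had 21973 to 23306 genes with at least 1 count, and the other 8 had 23494 to 27097. All WT libraries are numbered 1 to 10 and all KO libraries 13 to 22, so library order cannot be told apart from the genotype. The transcript of the inactive X chromosome, Xist, was present in all 6 WT libraries and in both KO 2 libraries. The Y-linked Ddx3y was 11.2 to 38.9 CPM in CD41pos WT 3 and 4 and CD41neg WT 2 and 3, which also held 113 to 339 CPM of Xist. Transcripts of both sexes were thus present in each of them, and a WT library need not stand for 1 animal. In KO 1 and KO 3 Ddx3y was 83.4 to 103 CPM with about 1 CPM of Xist. The sexes were thus not balanced between the genotypes, and their effects cannot be fully told apart. With Y-linked level as a covariate KO against WT called 2901 genes in CD41pos and 1346 in CD41neg cells, beside 3309 and 1517 without it.

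**Figure D1:**
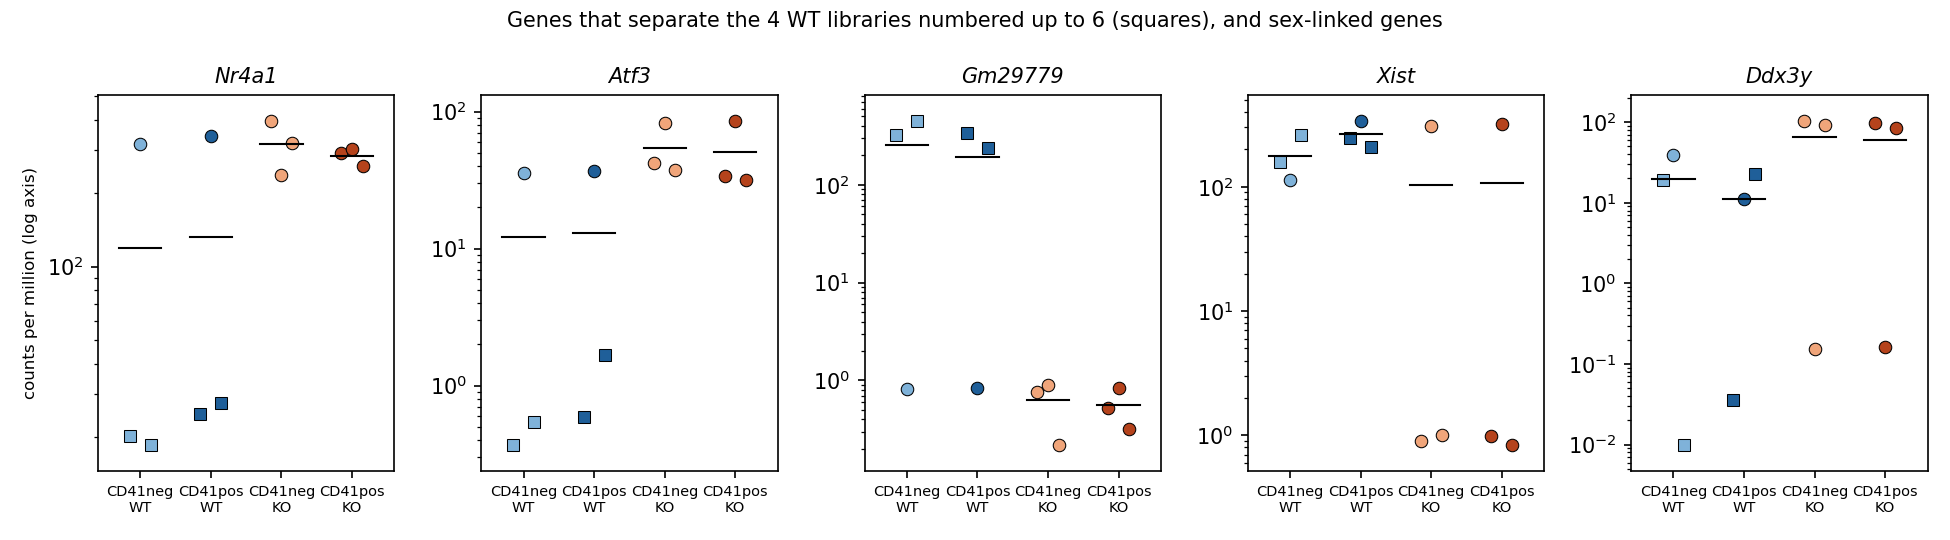
Normalised counts in CPM (log axis) of 3 genes that separate 4 WT libraries and of the sex-linked genes Xist and Ddx3y, 1 point per library with the group mean as a line; squares are the 4 WT libraries numbered up to 6 and a value of 0 is drawn at 0.01. Nr4a1 lay between 18.6 and 27.7 CPM in the squares and between 237 and 396 CPM in the circles.

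Runx1, the targeted gene, had a higher gene total in the KO groups. It measured 326 ± 55.9 against 149 ± 9.23 CPM in CD41pos HSCs and 164 ± 7.04 against 80.1 ± 12.9 CPM in CD41neg HSCs, with every KO library above every WT library of its gate. The log2 fold changes were 1.13 ± 0.15 (adjusted p = 0.00201) and 1.03 ± 0.15 (adjusted p = 0.00368). A gene total also counts reads from exons that remain after recombination, and the deleted part of the gene is not given in the sources used here, so these totals cannot check the deletion. Itga2b, which encodes the sorted antigen, followed the gate in both genotypes. In WT it measured 621 ± 65.9 against 103 ± 47.0 CPM (log2 fold change 2.59 ± 0.29, adjusted p = 0.000906). In KO the levels were 1118 ± 131 against 247 ± 30.2 CPM (2.18 ± 0.29, adjusted p = 0.00181). Runx3 rose in KO in both gates (0.40 and 0.52, adjusted p = 0.0457 and 0.030). Both Runx3 calls were lost with the term for the 4 WT libraries, at 0.25 ± 0.13 and 0.36 ± 0.13 (adjusted p = 0.164 and 0.0976). They were also lost in 9 and 7 of the 12 fits that leave out 1 library, at most to adjusted p-values of 0.146 without CD41pos KO 3 and 0.0935 without CD41neg KO 1. Runx2 did not pass in KO against WT, at -0.09 ± 0.25 (adjusted p = 0.822) in CD41pos and 0.48 ± 0.25 (adjusted p = 0.246) in CD41neg HSCs. It did not pass between gates either, at 0.51 ± 0.25 (adjusted p = 0.268) in WT and -0.07 ± 0.25 (adjusted p = 0.974) in KO.

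In the mm10 build, as spans of the whole annotated protein-coding gene, Runx1 lies on chromosome 16, 92601466 to 92826149, minus strand. Itga2b lies on chromosome 11, 102453297 to 102470122, minus strand. The genes described most fully below were placed in the same way. Prss34 lies on chromosome 17, 25298394 to 25300165, plus strand. Mcpt8 lies on chromosome 14, 56082166 to 56085273, minus strand. Alox12 lies on chromosome 11, 70241457 to 70255353, minus strand. Treml1 lies on chromosome 17, 48359916 to 48367176, plus strand. Thbs1 lies on chromosome 2, 118111876 to 118127133, plus strand. Podxl lies on chromosome 6, 31519488 to 31563981, minus strand. Chst1 lies on chromosome 2, 92599707 to 92615250, plus strand. Hs3st1 lies on chromosome 5, 39613935 to 39755475, minus strand. Col1a1 lies on chromosome 11, 94936224 to 94953042, plus strand. Pf4 lies on chromosome 5, 90772435 to 90773383, plus strand. Gp1bb lies on chromosome 16, 18620317 to 18622403, minus strand. Clu lies on chromosome 14, 65968483 to 65981547, plus strand.

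**Figure D2:**
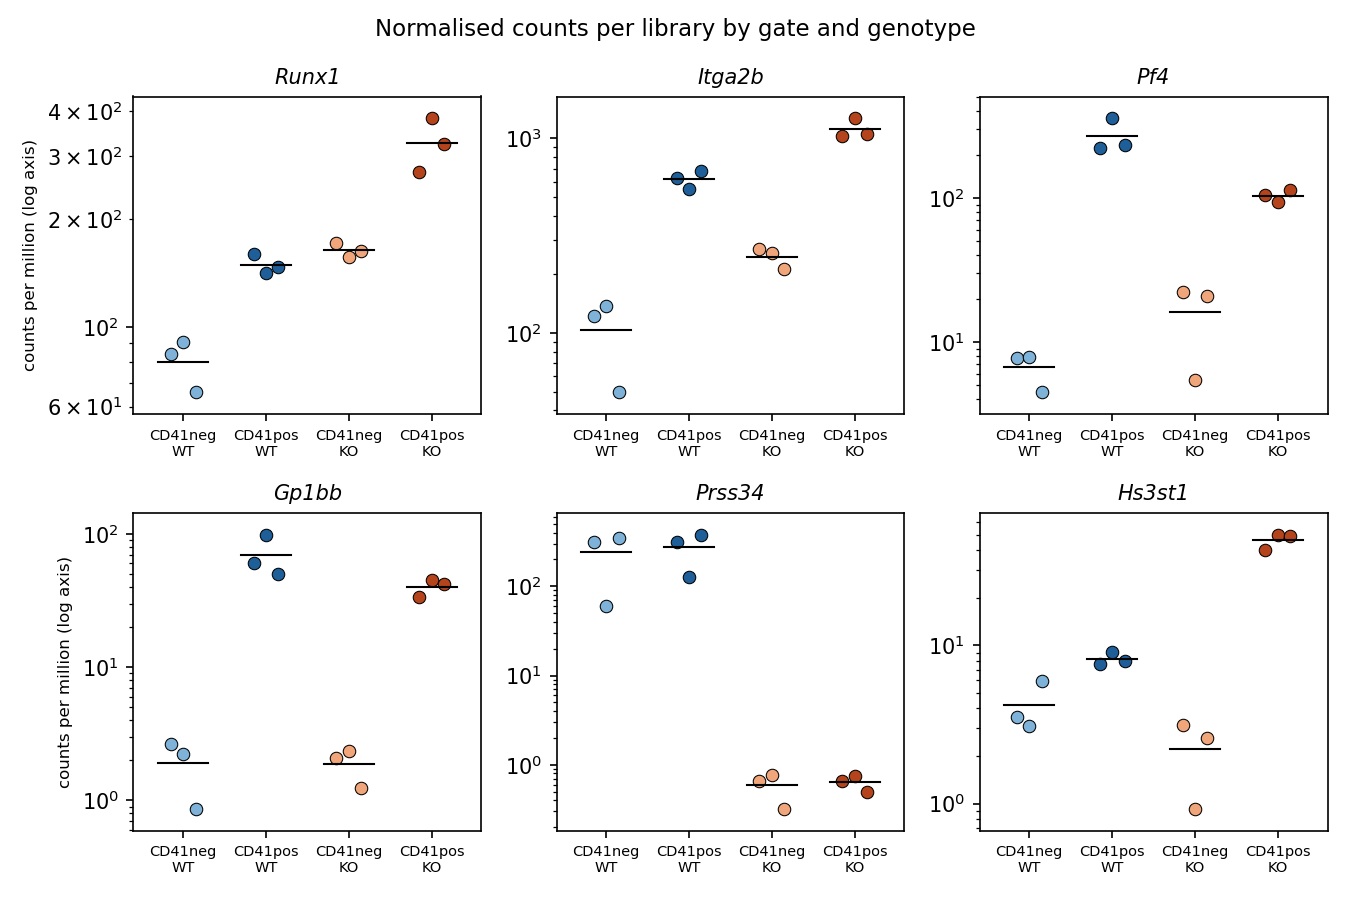
Normalised counts in CPM (log axis) of 6 genes by gate and genotype, 1 point per library with the group mean as a line. Runx1 and Itga2b were highest in CD41pos KO, Prss34 was below 1 CPM in KO libraries and Hs3st1 averaged 46.6 CPM in CD41pos KO against 8.20 CPM in CD41pos WT.

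The effect of the genotype on CD41pos HSCs, the fraction carrying the megakaryocyte-associated antigen, was asked by comparing CD41pos KO with CD41pos WT. Alox12, the platelet lipoxygenase, rose in KO from 3.15 ± 1.45 to 26.9 ± 2.98 CPM (3.09 ± 0.51, adjusted p = 0.00392). Treml1, a platelet granule receptor, rose from 43.7 ± 14.1 to 135 ± 6.37 CPM (1.63 ± 0.25, adjusted p = 0.00323). Thbs1, encoding thrombospondin, rose from 28.2 ± 32.1 to 235 ± 96.3 CPM (3.06 ± 0.82, adjusted p = 0.0264). Podxl, a cell-surface sialomucin, rose from 28.0 ± 6.74 to 212 ± 42.7 CPM (2.92 ± 0.31, adjusted p = 0.000935). The basophil protease genes Prss34 and Mcpt8 were below 1 CPM in every KO library. Prss34 fell from 274 ± 131 to 0.634 ± 0.132 CPM (-8.75 ± 0.76, adjusted p = 0.000466). Mcpt8 fell from 93.9 ± 34.0 to 0.572 ± 0.301 CPM (-7.35 ± 0.74, adjusted p = 0.000804). The 8 highest changes also included the sulfotransferase genes Chst1 (3.20 ± 0.46) and Hs3st1 (2.51 ± 0.37). Tnfaip3, an NF-kB inhibitor gene, was at 2.86 ± 0.53, Mylk3 at 2.59 ± 0.42 and Slc4a1, the red-cell anion exchanger gene, at 2.75 ± 0.70. The 8 lowest held Fcer1a (-5.02 ± 0.83), the alpha chain of the IgE receptor, and the collagen genes Col1a1 (-7.24 ± 1.96) and Col1a2 (-4.29 ± 1.13). Jchain, which joins IgA and IgM, was at -4.17 ± 0.92 and Evc2 at -4.59 ± 0.69. Jchain measured 581 and 471 CPM in CD41pos WT 1 and 4, which stand apart, and 79.3 CPM in WT 3. Mir6949 (-6.93 ± 0.81), also among the lowest, lies inside Mcpt8, and its reads cannot be told from those of Mcpt8. With the term for the 4 WT libraries the calls for Slc4a1, Col1a1 and Col1a2 were lost, at 1.72 ± 0.84, -2.39 ± 1.36 and -2.30 ± 0.98 (adjusted p = 0.153, 0.219 and 0.107). Other calls held with the term at other sizes, with -7.34 for Prss34, -6.28 for Mcpt8, -3.23 for Fcer1a, -1.76 for Jchain, 1.94 for Tnfaip3, 3.87 for Alox12, 4.98 for Thbs1 and 3.38 for Mylk3. Leaving out 1 library ended the calls for Thbs1 (0.0916 without CD41pos KO 2), Slc4a1 (0.0596 without CD41pos KO 2), Col1a1 (0.105 without CD41pos KO 2), Col1a2 (0.0894 without CD41pos KO 3) and Jchain (0.0618 without CD41pos KO 2), with the highest adjusted p for each.

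Among megakaryocyte and platelet genes, 8 of 30 measured members rose, 3 fell and 19 did not pass the test. For megakaryocyte and platelet genes, 10 rose and 4 fell when adjusted over the list alone, with an upward camera result (adjusted p = 0.0119, and adjusted p = 0.801 with an estimated correlation). Serpine2, a thrombin inhibitor gene, fell (-2.65 ± 0.38), while Gp5, a subunit of the von Willebrand factor receptor complex, rose (0.91 ± 0.16). Among cell cycle genes, 17 of 38 measured members rose, 0 fell and 21 did not pass the test. For cell cycle genes, 20 rose and 0 fell when adjusted over the list alone, with an upward camera result (adjusted p = 3.6e-06, and adjusted p = 0.515 with an estimated correlation). Top2a was at 1.12 ± 0.13 and Mki67 at 1.02 ± 0.13. Under the term for the 4 WT libraries 15 cell cycle genes were higher and 3 lower (adjusted p = 0.00584, and adjusted p = 0.743 with an estimated correlation). Among granulocyte-monocyte progenitor genes, 2 of 22 measured members rose, 10 fell and 10 did not pass the test. For granulocyte-monocyte progenitor genes, 2 rose and 12 fell when adjusted over the list alone, with a downward camera result (adjusted p = 1.37e-05, and adjusted p = 0.736 with an estimated correlation). Ly6c2 was at -2.80 ± 0.34, Cebpa at -1.61 ± 0.33 and Irf8 at -0.98 ± 0.19. Among endothelial and stromal markers, 0 of 18 measured members rose, 8 fell and 10 did not pass the test. For endothelial and stromal markers, 1 rose and 11 fell when adjusted over the list alone, with a downward camera result (adjusted p = 0.00597, and adjusted p = 0.486 with an estimated correlation). Cxcl12, a niche chemokine gene, fell from 90.3 ± 35.3 to 9.43 ± 1.47 CPM (-3.26 ± 0.37), and Sparc was at -2.78 ± 0.42. With the term for the 4 WT libraries 3 stromal members were higher and 5 lower, the list median was -2.29 against -1.81 without it, and the list did not pass (adjusted p = 0.0535). Among mast cell, basophil and eosinophil markers, 1 of 14 measured members rose, 5 fell and 8 did not pass the test. For mast cell, basophil and eosinophil markers, 3 rose and 6 fell when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.117, and adjusted p = 0.801 with an estimated correlation). Cpa3 and Ms4a2, chosen after their values were seen, were at 1.05 ± 0.39 (adjusted p = 0.0784) and 1.03 ± 0.36 (adjusted p = 0.0676). Both passed with the term for the 4 WT libraries, at 1.94 and 1.72 (adjusted p = 0.00458 and 0.0121). Among immediate early and stress genes, 1 of 25 measured members rose, 0 fell and 24 did not pass the test. For immediate early and stress genes, 1 rose and 0 fell when adjusted over the list alone, with an upward camera result (adjusted p = 0.00144, and adjusted p = 0.835 with an estimated correlation). The direction of the immediate early list turned with the term for the 4 WT libraries (adjusted p = 0.131), and the call was lost without CD41pos WT 4 (adjusted p = 0.0732). Among ribosomal protein genes, 0 of 82 measured members rose, 1 fell and 81 did not pass the test. For ribosomal protein genes, 0 rose and 0 fell when adjusted over the list alone, with a downward camera result (adjusted p = 8.49e-10, and adjusted p = 0.835 with an estimated correlation). Among oxidative phosphorylation genes, 1 of 95 measured members rose, 4 fell and 90 did not pass the test. For oxidative phosphorylation genes, 0 rose and 1 fell when adjusted over the list alone, with a downward camera result (adjusted p = 3.6e-06, and adjusted p = 0.895 with an estimated correlation). With the term 32 ribosomal protein genes and 21 oxidative phosphorylation genes were lower (adjusted p = 5.97e-13 and 1.23e-08, and adjusted p = 0.743 for each with an estimated correlation), and the contrast then leans on CD41pos WT 3. That library had a mean log2 CPM of 8.68 over ribosomal protein genes, against 7.83 and 7.74 in CD41pos WT 1 and 4 and 7.58 to 7.64 in CD41pos KO, and of 7.15 over oxidative phosphorylation genes, against 6.44, 6.35 and 6.24 to 6.29. Without it the lists had adjusted p = 0.00019 and 0.0443. Among the other lists above, the term gave 10 higher and 4 lower megakaryocyte and platelet genes, 1 and 8 granulocyte-monocyte progenitor genes, 4 and 4 mast cell, basophil and eosinophil markers, and 0 and 4 immediate early and stress genes. Among T and NK cell markers, 0 of 18 measured members rose, 1 fell and 17 did not pass the test. For T and NK cell markers, 0 rose and 1 fell when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.456, and adjusted p = 0.953 with an estimated correlation). Among monocyte, macrophage and dendritic cell markers, 0 of 23 measured members rose, 2 fell and 21 did not pass the test. For monocyte, macrophage and dendritic cell markers, 0 rose and 2 fell when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.0587, and adjusted p = 0.835 with an estimated correlation). With the term these 2 marker lists passed downward (adjusted p = 0.0257 and 0.0309), with medians of -1.41 against -0.56 and -0.84 against -0.41 without it, and each had adjusted p = 0.743 with an estimated correlation.

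Across all 19395 genes tested, 3309 passed an adjusted p of 0.05 (1899 higher and 1410 lower in KO), 1417 of them by at least a log2 change of 1 (666 higher and 751 lower), and 6863 had an unadjusted p below 0.05. In 8590 genes (44.3%) the 3 KO libraries lay all above or all below the 3 WT libraries, against 10% for chance. The count was 4572 with the term for the 4 WT libraries, 2664 of the genes remaining in the same direction, but each gate then rests on 1 WT library outside the 4 and on their shared shift. It was 2154 with only the groups compared, 2437 on log2(TPM + 1) (1674 higher and 763 lower) and 7469 (4306 higher and 3163 lower) without the 4 libraries, where 1 WT library per gate is assumed to vary like the other groups. It fell to 1580, 965 and 1175 without CD41pos KO 1, 2 and 3.

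KO was compared with WT in CD41neg HSCs in the same way, and Prss34 and Mcpt8 were again below 1 CPM in every KO library. Prss34 fell from 241 ± 158 to 0.588 ± 0.235 CPM (-8.68 ± 0.76, adjusted p = 0.000409). Mcpt8 fell from 76.0 ± 52.5 to 0.208 ± 0.0288 CPM (-8.50 ± 0.81, adjusted p = 0.000409). Treml1 rose from 3.11 ± 0.941 to 25.1 ± 4.79 CPM (3.01 ± 0.27, adjusted p = 0.000409). Plek, encoding the platelet kinase substrate pleckstrin, rose from 18.9 ± 9.03 to 112 ± 19.1 CPM (2.56 ± 0.40, adjusted p = 0.00528). The other highest were Clec10a (3.19 ± 0.56), Chst1 (2.52 ± 0.44) and the thrombin receptor gene F2rl2 (2.35 ± 0.43). Rn7s1 (2.35 ± 0.26) and Rn7s2 (2.33 ± 0.26) are near-identical copies of a 7S RNA gene, and their values are uncertain for that reason. The other lowest were Col1a1 (-8.14 ± 2.03), the bone sialoprotein gene Ibsp (-6.77 ± 0.82) and Fcer1a (-6.64 ± 0.94). Ccr10 was at -5.29 ± 0.96, Derl3 at -5.11 ± 0.75 and Mocs1 at -4.97 ± 0.84. Mocs1 measured 38.5 to 73.6 CPM in the 4 WT libraries that stand apart and 1.24 to 7.54 CPM in the other 8. In CD41neg WT 2 and 4, which belong to the 4, Ccr10 measured 24.6 and 15.8 CPM against 2.18 CPM in WT 3, and Derl3 57.3 and 35.6 against 4.81 CPM. The plasma-cell genes Jchain (2822 and 2346 against 276 CPM) and Mzb1 (128 and 94.1 against 6.83 CPM), looked at after their values were seen, were high in the same libraries. The term for the 4 libraries put the changes at -2.81 for Ccr10, -3.93 for Derl3, -2.43 for Mocs1, -4.65 for Fcer1a, -7.05 for Prss34 and -7.05 for Mcpt8, and these calls held. The call for Col1a1 was lost with that term, at -2.95 ± 1.43 (adjusted p = 0.19). Itga2b rose from 103 ± 47.0 to 247 ± 30.2 CPM (1.26 ± 0.28, adjusted p = 0.0223). With the term the Itga2b change was 1.12 ± 0.34 and did not pass (adjusted p = 0.0631). In CD41pos HSCs the change of Itga2b with the genotype was 0.85 ± 0.28 (adjusted p = 0.0547). Leaving out 1 library ended the calls in CD41neg cells for Itga2b (0.0725 without CD41neg KO 1), Col1a1 (0.135 without CD41neg WT 2), Ccr10 (0.0514 without CD41neg KO 3), Ms4a3 (0.051 without CD41neg KO 3), Nop2 (0.0576 without CD41neg KO 3) and Utp20 (0.0863 without CD41neg KO 3), with the highest adjusted p for each.

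Among endothelial and stromal markers, 0 of 18 measured members rose, 11 fell and 7 did not pass the test. For endothelial and stromal markers, 1 rose and 13 fell when adjusted over the list alone, with a downward camera result (adjusted p = 6.78e-08, and adjusted p = 0.22 with an estimated correlation). Cxcl12 fell from 103 ± 37.5 to 4.83 ± 1.82 CPM (-4.41 ± 0.39, adjusted p = 0.000409). The leptin receptor gene Lepr was at -3.32 ± 0.56, and Flt4, a receptor of lymphatic and sinusoidal endothelium, at -2.73 ± 0.37. Among granulocyte-monocyte progenitor genes, 0 of 22 measured members rose, 7 fell and 15 did not pass the test. For granulocyte-monocyte progenitor genes, 1 rose and 11 fell when adjusted over the list alone, with a downward camera result (adjusted p = 1.37e-05, and adjusted p = 0.736 with an estimated correlation). Ly6c2 was at -2.32 ± 0.33 and Ms4a3 at -1.74 ± 0.34. Among monocyte, macrophage and dendritic cell markers, 0 of 23 measured members rose, 3 fell and 20 did not pass the test. For monocyte, macrophage and dendritic cell markers, 0 rose and 3 fell when adjusted over the list alone, with a downward camera result (adjusted p = 0.00465, and adjusted p = 0.801 with an estimated correlation). Among mature neutrophil markers, 0 of 15 measured members rose, 0 fell and 15 did not pass the test. For mature neutrophil markers, 0 rose and 0 fell when adjusted over the list alone, with a downward camera result (adjusted p = 0.00038, and adjusted p = 0.801 with an estimated correlation). Among genes high in aged stem cells, 1 of 30 measured members rose, 5 fell and 24 did not pass the test. For genes high in aged stem cells, 1 rose and 12 fell when adjusted over the list alone, with a downward camera result (adjusted p = 0.000237, and adjusted p = 0.388 with an estimated correlation). With the term for the 4 WT libraries the median was -0.49 against -0.72 and this call was lost (adjusted p = 0.0789). Among ribosome biogenesis genes, 1 of 36 measured members rose, 4 fell and 31 did not pass the test. For ribosome biogenesis genes, 2 rose and 8 fell when adjusted over the list alone, with a downward camera result (adjusted p = 0.000247, and adjusted p = 0.736 with an estimated correlation). Nop2 was at -0.60 ± 0.11 and Utp20 at 0.65 ± 0.16. Among ribosomal protein genes, 0 of 82 measured members rose, 0 fell and 82 did not pass the test. For ribosomal protein genes, 0 rose and 0 fell when adjusted over the list alone, with a downward camera result (adjusted p = 0.00049, and adjusted p = 0.923 with an estimated correlation). Among oxidative phosphorylation genes, 0 of 95 measured members rose, 1 fell and 94 did not pass the test. For oxidative phosphorylation genes, 0 rose and 1 fell when adjusted over the list alone, with a downward camera result (adjusted p = 1.37e-05, and adjusted p = 0.895 with an estimated correlation). Among glycolysis genes, 0 of 17 measured members rose, 0 fell and 17 did not pass the test. For glycolysis genes, 0 rose and 5 fell when adjusted over the list alone, with a downward camera result (adjusted p = 0.0015, and adjusted p = 0.427 with an estimated correlation). With the term 6 glycolysis genes were lower (adjusted p = 0.00078, and adjusted p = 0.433 with an estimated correlation). Among interferon response genes, 2 of 35 measured members rose, 1 fell and 32 did not pass the test. For interferon response genes, 2 rose and 1 fell when adjusted over the list alone, with an upward camera result (adjusted p = 0.0114, and adjusted p = 0.829 with an estimated correlation). Among immediate early and stress genes, 1 of 25 measured members rose, 0 fell and 24 did not pass the test. For immediate early and stress genes, 1 rose and 0 fell when adjusted over the list alone, with an upward camera result (adjusted p = 2.11e-05, and adjusted p = 0.808 with an estimated correlation). The immediate early call was lost with the term, where the median was -0.0097 against 0.83 (adjusted p = 0.988). Among megakaryocyte and platelet genes, 5 of 30 measured members rose, 2 fell and 23 did not pass the test. For megakaryocyte and platelet genes, 7 rose and 2 fell when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.073, and adjusted p = 0.835 with an estimated correlation). With the term this list passed upward (adjusted p = 0.00778, and adjusted p = 0.743 with an estimated correlation), with a median of 0.66 against 0.18 without it. Among mast cell, basophil and eosinophil markers, 1 of 14 measured members rose, 4 fell and 9 did not pass the test. For mast cell, basophil and eosinophil markers, 2 rose and 9 fell when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.119, and adjusted p = 0.835 with an estimated correlation). Cpa3, chosen after its values were seen, was at 1.03 ± 0.39 (adjusted p = 0.118), and passed with the term at 1.92 (adjusted p = 0.00941). Counts under the term were 1 higher and 8 lower for stromal markers, 0 and 4 for granulocyte-monocyte progenitor genes, 2 and 8 for ribosome biogenesis genes, and 4 and 0 for interferon response genes. List calls lost without 1 library were those for interferon response genes (0.103 without CD41neg KO 2 and 0.0642 without CD41neg WT 3) and monocyte, macrophage and dendritic cell markers (0.114 without CD41neg KO 2). Without CD41neg WT 4 the calls for ribosomal protein genes and oxidative phosphorylation genes were lost (adjusted p = 0.417 and 0.0639).

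The remaining lists passed camera in none of the 5 comparisons. Of 32 haematopoietic stem cell genes, 3 rose and 5 fell in CD41pos HSCs (3 and 5 adjusted over the list alone, camera adjusted p = 0.249). In CD41neg HSCs 1 rose and 3 fell among haematopoietic stem cell genes (4 and 6 adjusted over the list alone, camera adjusted p = 0.116). Of 10 RUNX family and partners, 4 rose and 0 fell in CD41pos HSCs (4 and 1 adjusted over the list alone, camera adjusted p = 0.0822). In CD41neg HSCs 2 rose and 0 fell among RUNX family and partners (3 and 0 adjusted over the list alone, camera adjusted p = 0.0637). Of 31 NF-kB and Toll-like receptor genes, 4 rose and 2 fell in CD41pos HSCs (4 and 2 adjusted over the list alone, camera adjusted p = 0.513). In CD41neg HSCs 2 rose and 0 fell among NF-kB and Toll-like receptor genes (2 and 0 adjusted over the list alone, camera adjusted p = 0.123). Of 20 p53 target genes, 2 rose and 1 fell in CD41pos HSCs (4 and 2 adjusted over the list alone, camera adjusted p = 0.871). In CD41neg HSCs 1 rose and 1 fell among p53 target genes (1 and 1 adjusted over the list alone, camera adjusted p = 0.95). Of 32 adhesion and niche receptors, 8 rose and 6 fell in CD41pos HSCs (8 and 6 adjusted over the list alone, camera adjusted p = 0.532). In CD41neg HSCs 3 rose and 1 fell among adhesion and niche receptors (7 and 4 adjusted over the list alone, camera adjusted p = 0.939). With the term for the 4 WT libraries 8 of these receptors were higher and 2 lower in CD41neg KO, and the list did not pass (adjusted p = 0.182). Of 13 mature B cell markers, 0 rose and 0 fell in CD41pos HSCs (0 and 0 adjusted over the list alone, camera adjusted p = 0.464). In CD41neg HSCs 0 rose and 1 fell among mature B cell markers (0 and 3 adjusted over the list alone, camera adjusted p = 0.422).

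In this gate 1517 of 19395 genes passed (747 higher and 770 lower), 827 by at least a log2 change of 1 (369 higher and 458 lower), with 5108 at an unadjusted p below 0.05, and the 3 libraries of each genotype did not overlap in 6885 genes (35.5%, against 10% for chance). Of the genes called higher in CD41pos KO, 510 were also higher in CD41neg KO, where independent lists would share 73.1, and 463 were lower in both against 56.0; 2 moved in opposite directions. The 2 comparisons share no library, though the KO libraries of both gates carry the same animal labels and each WT arm holds 2 of the 4 libraries that stand apart. Each CD41neg KO library also had a higher total (50342270 or more counts) than each CD41neg WT library (50239678 or fewer). Across genes, which are not independent replicates, Pearson's r of the fold changes was 0.60 and Spearman's rho 0.63. The count was 1683 with the term for the 4 WT libraries (922 remaining in the same direction), 1658 without these libraries and 2989 with DESeq2. It moved to 3856 without CD41pos WT 3, to 959 and 462 without CD41neg WT 2 and 4, to 966, 976 and 859 without CD41pos KO 1, 2 and 3, and to 524, 657 and 341 without CD41neg KO 1, 2 and 3.

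**Figure D3:**
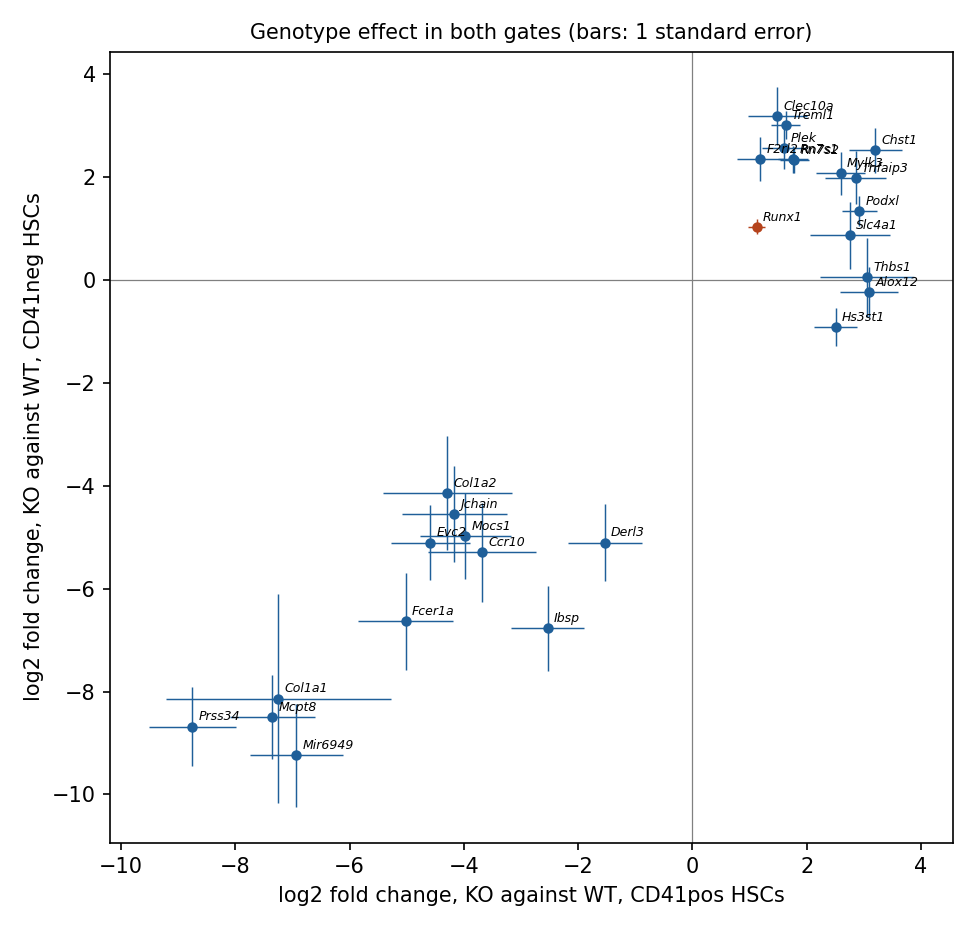
Log2 fold change of KO against WT in CD41pos HSCs (horizontal) and CD41neg HSCs (vertical) for the genes with the highest and lowest changes that are reported here and Runx1, with bars of 1 standard error. Prss34 and Mcpt8 lay at the lower left in both gates (-8.75 and -7.35 in CD41pos, -8.68 and -8.50 in CD41neg HSCs).

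CD41pos and CD41neg HSCs of WT mice were compared to describe what distinguishes the gates in controls. Pf4, platelet factor 4, was higher in CD41pos cells, with 270.1 ± 75.4 against 6.71 ± 1.95 CPM (5.33 ± 0.48, adjusted p = 0.000178). Gp1bb, a subunit of the von Willebrand factor receptor, measured 69.9 ± 25.4 against 1.92 ± 0.927 CPM (5.19 ± 0.43, adjusted p = 0.000132). The carbonic anhydrase gene Car1, used in red cells, was lower, with 564 ± 80.3 against 1864 ± 401 CPM (adjusted p = 0.00198). Klf1, the erythroid transcription factor, was at -1.48 ± 0.28 and Ermap, an erythroid membrane protein, at -2.44 ± 0.27. Runx1 was higher in CD41pos cells (0.90 ± 0.15, adjusted p = 0.00589), as was Runx3 (0.54 ± 0.13, adjusted p = 0.0281). The other highest were Mrvi1 (5.38 ± 0.69), Pde10a (4.44 ± 0.81) and Slc35d3 (4.33 ± 0.48). Kcnj5 was at 4.28 ± 0.59, Robo3 at 4.05 ± 0.27 and F2rl2 at 3.84 ± 0.46. The lowest were Ushbp1 (-3.59 ± 0.82), Gpm6a (-3.38 ± 0.84) and Flt4 (-3.17 ± 0.37). Irf4 and Pou2af1, factors of plasma and lymphoid cells, were at -3.22 ± 0.44 and -3.07 ± 0.65. In CD41neg WT 2 and 4, which stand apart, Irf4 measured 17.7 and 12.1 CPM against 6.54 CPM in WT 3, and Pou2af1 51.3 and 24.1 against 9.29 CPM. Jchain (2822 and 2346 against 276 CPM) and Mzb1 (128 and 94.1 against 6.83 CPM) were high in the same 2 libraries. The basement-membrane gene Nid1 was at -3.05 ± 0.62, Rgs4 at -3.02 ± 0.46 and Tspan7 at -2.96 ± 0.77. In the WT gates the calls lost without 1 library, with the highest adjusted p, were Runx3 (0.0811 without CD41neg WT 2), Ushbp1 (0.0771 without CD41neg WT 4), Gpm6a (0.0998 without CD41pos WT 4), Pou2af1 (0.0675 without CD41neg WT 2), Nid1 (0.0536 without CD41pos WT 4), Tspan7 (0.109 without CD41pos WT 4) and Vwf (0.0962 without CD41neg WT 2).

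Among megakaryocyte and platelet genes, 19 of 30 measured members were higher, 0 were lower and 11 did not pass the test. For megakaryocyte and platelet genes, 22 were higher and 0 were lower when adjusted over the list alone, with an upward camera result (adjusted p = 6.76e-23, and adjusted p = 0.0575 with an estimated correlation). Treml1 was at 3.81 ± 0.28, Sdpr (also called Cavin2) at 3.47 ± 0.25, Vwf at 2.05 ± 0.49 and Gp9 at 2.11 ± 0.15. Among erythroid genes, 0 of 20 measured members were higher, 13 were lower and 7 did not pass the test. For erythroid genes, 0 were higher and 15 were lower when adjusted over the list alone, with a downward camera result (adjusted p = 1.39e-14, and adjusted p = 0.122 with an estimated correlation). Trib2 was at -2.26 ± 0.31. Among granulocyte-monocyte progenitor genes, 10 of 22 measured members were higher, 0 were lower and 12 did not pass the test. For granulocyte-monocyte progenitor genes, 17 were higher and 0 were lower when adjusted over the list alone, with an upward camera result (adjusted p = 8.79e-13, and adjusted p = 0.388 with an estimated correlation). The granule protease genes Ctsg and Prtn3 were at 1.91 ± 0.33 and 1.63 ± 0.29. Among ribosome biogenesis genes, 0 of 36 measured members were higher, 15 were lower and 21 did not pass the test. For ribosome biogenesis genes, 0 were higher and 26 were lower when adjusted over the list alone, with a downward camera result (adjusted p = 4.95e-15, and adjusted p = 0.29 with an estimated correlation). Ncl, encoding a nucleolar protein, was at -0.59 ± 0.10 and Mybbp1a at -0.76 ± 0.14. Among megakaryocyte-erythroid transcription factors, 4 of 14 measured members were higher, 1 were lower and 9 did not pass the test. For megakaryocyte-erythroid transcription factors, 6 were higher and 2 were lower when adjusted over the list alone, with an upward camera result (adjusted p = 0.0141, and adjusted p = 0.69 with an estimated correlation). Mef2c was at 1.33 ± 0.12. Among genes high in aged stem cells, 9 of 30 measured members were higher, 1 were lower and 20 did not pass the test. For genes high in aged stem cells, 11 were higher and 3 were lower when adjusted over the list alone, with an upward camera result (adjusted p = 0.0142, and adjusted p = 0.69 with an estimated correlation). Among RUNX1-linked platelet genes, 3 of 15 measured members were higher, 1 were lower and 11 did not pass the test. For RUNX1-linked platelet genes, 3 were higher and 2 were lower when adjusted over the list alone, with an upward camera result (adjusted p = 0.0146, and adjusted p = 0.388 with an estimated correlation). Among cyclins and CDK inhibitors, 3 of 14 measured members were higher, 0 were lower and 11 did not pass the test. For cyclins and CDK inhibitors, 5 were higher and 0 were lower when adjusted over the list alone, with an upward camera result (adjusted p = 0.016, and adjusted p = 0.427 with an estimated correlation). Among lymphoid priming genes, 1 of 25 measured members were higher, 3 were lower and 21 did not pass the test. For lymphoid priming genes, 1 were higher and 5 were lower when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.101, and adjusted p = 0.895 with an estimated correlation). With the term for the 4 WT libraries the lymphoid priming list passed downward (adjusted p = 0.0134, and adjusted p = 0.761 with an estimated correlation). Among ribosomal protein genes, 0 of 82 measured members were higher, 0 were lower and 82 did not pass the test. For ribosomal protein genes, 0 were higher and 0 were lower when adjusted over the list alone, with an upward camera result (adjusted p = 0.016, and adjusted p = 0.953 with an estimated correlation). Without CD41pos WT 3 the ribosomal protein result turned downward (adjusted p = 0.00123), and without CD41neg WT 2 or 3 it did not pass (adjusted p = 0.356 and 0.342). Other list calls lost without 1 library were those for megakaryocyte-erythroid transcription factors (0.123 without CD41pos WT 3), RUNX1-linked platelet genes (0.0588 without CD41neg WT 4 and 0.0641 without CD41pos WT 1), genes high in aged stem cells (0.0736 without CD41neg WT 3 and 0.0619 without CD41pos WT 4) and cyclins and CDK inhibitors (0.0855 without CD41neg WT 4).

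Here 1084 genes passed (528 higher and 556 lower in CD41pos cells), 582 by at least a log2 change of 1 (318 higher and 264 lower), with 4199 at an unadjusted p below 0.05 and 4427 (22.8%, against 10% for chance) separated between gates. Each gate held 2 of the 4 WT libraries that stand apart, and with their term 1604 genes passed, 1077 of the 1084 among them. The count was 201 with only the groups compared, 2301 with DESeq2 and 4672 (1772 higher and 2900 lower) without the 4 libraries, where each gate keeps 1 WT library. The count moved to 684 without CD41pos WT 1, to 550 and 442 without CD41neg WT 2 and 4, to 640 without CD41pos KO 3 and to 688 without CD41neg KO 3.

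The gates of KO mice were compared to describe the same contrast in that genotype. CD41pos KO cells had more Clu, encoding a secreted chaperone held in platelet granules, with 97.9 ± 21.5 against 2.94 ± 2.12 CPM (5.06 ± 0.44, adjusted p = 0.000119). Sdpr, encoding a caveolar protein, measured 175 ± 17.4 against 7.90 ± 0.981 CPM (4.47 ± 0.26, adjusted p = 1.0e-05). Gp1bb was at 4.42 ± 0.41 (adjusted p = 0.000203). Hs3st1 measured 46.6 ± 5.56 against 2.22 ± 1.15 CPM (4.39 ± 0.41, adjusted p = 0.000203), beside 8.20 ± 0.730 against 4.18 ± 1.52 CPM in WT. Pf4 was 104 ± 9.82 against 16.1 ± 9.30 CPM (2.69 ± 0.43, adjusted p = 0.00524). Runx1 was higher in CD41pos cells (0.99 ± 0.15, adjusted p = 0.00354), and Runx3 did not pass (0.42 ± 0.12, adjusted p = 0.109, and 0.048 with the term for the 4 WT libraries). The other highest were Proser2 (4.56 ± 0.37), Kcnj5 (4.46 ± 0.57), Robo3 (4.20 ± 0.26) and the nitric oxide receptor gene Gucy1b3 (4.30 ± 0.73). The lowest were Slc25a21 (-2.72 ± 0.32), Atp1b2 (-2.55 ± 0.28), Slc16a11 (-2.46 ± 0.57) and Slc37a3 (-2.45 ± 0.57). The metallothionein gene Mt2 was at -2.44 ± 0.52, the red-cell pyruvate kinase gene Pklr at -2.44 ± 0.33, Ermap at -2.43 ± 0.27 and Kcng2 at -2.41 ± 0.34. In the KO gates the calls lost without 1 library, with the highest adjusted p, were Gucy1b3 (0.0541 without CD41neg KO 3), Slc16a11 (0.177 without CD41pos KO 2), Slc37a3 (0.174 without CD41pos KO 2), Mt2 (0.134 without CD41pos KO 2), Mpo (0.0561 without CD41neg KO 3) and Ikzf1 (0.0638 without CD41pos KO 2).

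Among megakaryocyte and platelet genes, 20 of 30 measured members were higher, 0 were lower and 10 did not pass the test. For megakaryocyte and platelet genes, 26 were higher and 1 were lower when adjusted over the list alone, with an upward camera result (adjusted p = 1.08e-37, and adjusted p = 0.0312 with an estimated correlation). Alox12 was at 3.75 ± 0.52 and the fibrinogen receptor gene Itgb3 at 3.50 ± 0.44. Among the 130 list tests of all comparisons, this was the only call to hold with an estimated correlation, and with the term for the 4 WT libraries it did not (adjusted p = 0.0785 with an estimated correlation). Among erythroid genes, 0 of 20 measured members were higher, 12 were lower and 8 did not pass the test. For erythroid genes, 0 were higher and 14 were lower when adjusted over the list alone, with a downward camera result (adjusted p = 4.11e-20, and adjusted p = 0.0575 with an estimated correlation). Klf1 was at -1.76 ± 0.29 and Car1 at -2.18 ± 0.24. Among granulocyte-monocyte progenitor genes, 6 of 22 measured members were higher, 0 were lower and 16 did not pass the test. For granulocyte-monocyte progenitor genes, 16 were higher and 0 were lower when adjusted over the list alone, with an upward camera result (adjusted p = 6.93e-14, and adjusted p = 0.388 with an estimated correlation). The myeloperoxidase gene Mpo was at 1.94 ± 0.35. Among genes high in aged stem cells, 8 of 30 measured members were higher, 2 were lower and 20 did not pass the test. For genes high in aged stem cells, 12 were higher and 3 were lower when adjusted over the list alone, with an upward camera result (adjusted p = 4.96e-05, and adjusted p = 0.388 with an estimated correlation). Fhl1 was at 3.23 ± 0.27. Among RUNX1-linked platelet genes, 4 of 15 measured members were higher, 0 were lower and 11 did not pass the test. For RUNX1-linked platelet genes, 6 were higher and 1 were lower when adjusted over the list alone, with an upward camera result (adjusted p = 0.000216, and adjusted p = 0.189 with an estimated correlation). Among lymphoid priming genes, 1 of 25 measured members were higher, 2 were lower and 22 did not pass the test. For lymphoid priming genes, 1 were higher and 6 were lower when adjusted over the list alone, with a downward camera result (adjusted p = 6.42e-06, and adjusted p = 0.454 with an estimated correlation). Ikzf1, a lymphoid transcription factor, was at -0.91 ± 0.16. Among cell cycle genes, 0 of 38 measured members were higher, 0 were lower and 38 did not pass the test. For cell cycle genes, 3 were higher and 1 were lower when adjusted over the list alone, with an upward camera result (adjusted p = 1.33e-10, and adjusted p = 0.388 with an estimated correlation). Among glycolysis genes, 0 of 17 measured members were higher, 0 were lower and 17 did not pass the test. For glycolysis genes, 9 were higher and 1 were lower when adjusted over the list alone, with an upward camera result (adjusted p = 8.08e-05, and adjusted p = 0.388 with an estimated correlation). Among cyclins and CDK inhibitors, 1 of 14 measured members were higher, 0 were lower and 13 did not pass the test. For cyclins and CDK inhibitors, 3 were higher and 0 were lower when adjusted over the list alone, with an upward camera result (adjusted p = 0.0119, and adjusted p = 0.391 with an estimated correlation). Among interferon response genes, 0 of 35 measured members were higher, 1 were lower and 34 did not pass the test. For interferon response genes, 0 were higher and 4 were lower when adjusted over the list alone, with a downward camera result (adjusted p = 0.000298, and adjusted p = 0.725 with an estimated correlation). Among ribosome biogenesis genes, 0 of 36 measured members were higher, 0 were lower and 36 did not pass the test. For ribosome biogenesis genes, 0 were higher and 0 were lower when adjusted over the list alone, with a downward camera result (adjusted p = 0.00289, and adjusted p = 0.808 with an estimated correlation). That call was lost without CD41neg KO 2 (adjusted p = 0.341). Among T and NK cell markers, 1 of 18 measured members were higher, 0 were lower and 17 did not pass the test. For T and NK cell markers, 2 were higher and 2 were lower when adjusted over the list alone, with a downward camera result (adjusted p = 0.00706, and adjusted p = 0.829 with an estimated correlation). Under the term 4 interferon response genes and 4 lymphoid priming genes were lower and 2 cell cycle genes higher.

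In KO, 541 genes passed (302 higher and 239 lower), 375 by at least a log2 change of 1 (203 higher and 172 lower), with 2615 at an unadjusted p below 0.05 and 5793 (29.9%, against 10% for chance) separated between gates. The main fit behind the 541 did not pair the KO libraries by animal label. With the animal label as a block 156 passed, and 607 with the WT libraries paired by library number instead. When the blocked model held the 6 KO libraries alone, a fit chosen after seeing the data, 2222 passed. The count was 1505 with only the groups compared, 1242 with DESeq2 and 1464 (915 higher and 549 lower) without the 4 WT libraries. Of the genes higher in CD41pos cells 192 were shared by both genotypes, against 8.22 for independent lists, and 167 of those lower, against 6.85; 1 gene moved in opposite directions. These comparisons share no library, and r across genes was 0.36 with rho 0.41. The count moved to 1041 without CD41pos WT 3, to 318, 196 and 212 without CD41pos KO 1, 2 and 3, and to 332 and 222 without CD41neg KO 1 and 3.

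**Figure D4:**
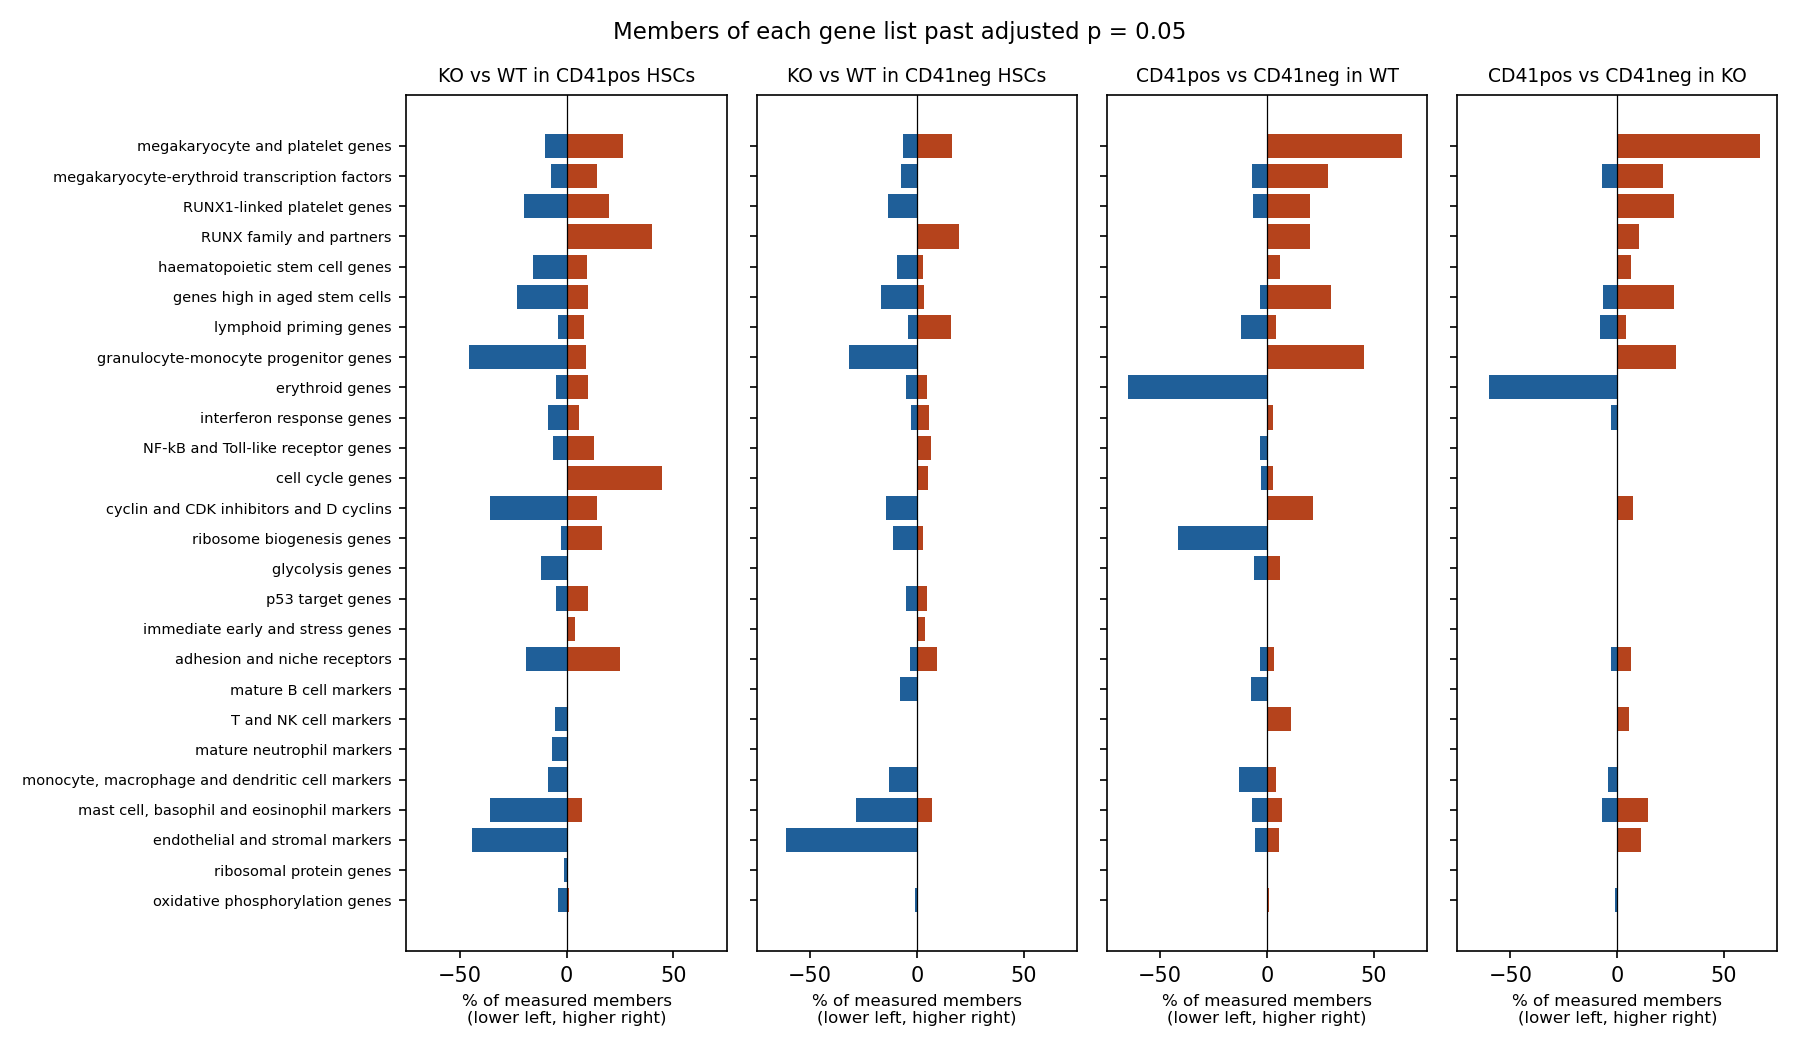
Share of the measured members of each gene list past an adjusted p of 0.05 in 4 comparisons, in percent, with higher members to the right in red and lower members to the left in blue. In the megakaryocyte and platelet list 19 of 30 members were higher in CD41pos WT cells and 20 of 30 in CD41pos KO cells.

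Whether the genotype acted differently in the gates was tested by the interaction of genotype and gate. For Runx1 the difference of the fold changes was 0.09 ± 0.21 (adjusted p = 0.961), and for Itga2b -0.41 ± 0.39 (adjusted p = 0.92), Runx2 -0.58 ± 0.36 (0.897) and Runx3 -0.12 ± 0.18 (0.946). No gene passed edgeR's quasi-likelihood test, while 1093 had an unadjusted p below 0.05; DESeq2's Wald test called 67, voom with quality weights 3, and limma-trend on log2(TPM + 1) and log2(TPM + 0.1) 7 and 26. Without the 4 WT libraries, a fit chosen after seeing the data in which each gate keeps 1 WT library, edgeR's test called 3368 genes (2349 higher and 1019 lower), and with the term for these libraries 0. The genes named next were chosen after their values were seen, and none passed. Adgrg6, an adhesion receptor gene, averaged 7.93 ± 3.14 CPM in CD41pos KO and 0.583 ± 0.193 CPM in CD41pos WT, against 0.965 ± 0.530 and 2.26 ± 0.646 CPM in CD41neg cells (interaction 4.98 ± 0.71, adjusted p = 0.141). Hs3st1 (3.42 ± 0.52, adjusted p = 0.155), Clu (2.81 ± 0.54, 0.452) and Alox12 (3.33 ± 0.69, 0.515) had higher estimates of the KO change in CD41pos cells, none past the threshold. For Pf4 the estimate was negative (-2.64 ± 0.58, adjusted p = 0.585): KO against WT was -1.38 ± 0.41 (adjusted p = 0.0372) in CD41pos and 1.26 ± 0.42 (adjusted p = 0.0808) in CD41neg HSCs. The Pf4 call in CD41pos cells was lost in 6 of the 12 fits that leave out 1 library, with the highest adjusted p for Pf4 (0.127 without CD41pos KO 2). On simulated counts, in which the shift of the 4 WT libraries entered only as added spread, the interaction test recovered 56.1% of 4-fold and 11.9% of 2-fold changes.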

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

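All tests of explanations in this part were chosen after the results were seen, while the list tests were planned.

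The difference between gates in the effect of the genotype was tested for each list, and 8 lists passed with the preset correlation, none of them with an estimated one. Ribosome biogenesis genes were relatively higher with KO in CD41pos cells (adjusted p = 4.44e-12, and 0.388 with an estimated correlation), as were cell cycle genes (1.63e-08, and 0.391) and endothelial and stromal markers (0.000361, and 0.388). Ribosomal protein genes went the other way (5.31e-05, and 0.91), although without CD41pos WT 3 the direction turned (0.114). Interferon response genes (0.016, and 0.835) and lymphoid priming genes (0.0489, and 0.835) were relatively lower, and genes high in aged stem cells (0.0416, and 0.762) relatively higher. Mature neutrophil markers had an upward result (0.0489, and 0.895) with a median of 0.08 and a mean of -0.01, so the signs differ. With the animal label as a fixed block, added after seeing the data, 6 of the 8 calls held. The neutrophil list turned in that fit (camera adjusted p = 0.534 over 78 tests). A random block, planned beforehand, also kept 6. With the term for the 4 WT libraries the calls for lymphoid priming genes (0.0752) and genes high in aged stem cells (0.0523) were lost, and immediate early and stress genes passed downward (0.00353, and 0.743 with an estimated correlation; 0.279 without the term). Leaving out 1 library ended the calls for interferon response genes (0.598 without CD41pos WT 4 at most), lymphoid priming genes (0.382 without CD41neg WT 4), genes high in aged stem cells (0.285 without CD41pos WT 3) and mature neutrophil markers (0.576 without CD41pos WT 1).

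The 4 WT libraries numbered up to 6 stood apart from the other 8. Library size is argued against, since 4 of the 4 totals lay within the range of the other 8, although fewer genes had a count in them (21973 to 23306 against 23494 to 27097). Immediate early and stress genes were lower in the 4 libraries (adjusted p = 5.66e-34, and adjusted p = 0.0388 with an estimated correlation), but the list holds Nr4a1 and Atf3, by which these libraries were recognised, so this value describes the split and decides nothing about its source. Other lists passed camera for this split with the preset correlation but not with an estimated one. Among these lists ribosomal protein genes (adjusted p = 4.0e-09, and 0.741), oxidative phosphorylation genes (1.49e-06, and 0.741) and T and NK cell markers (0.000117, and 0.628) were lower than in WT 3. Mean log2 CPM over ribosomal protein genes was 7.69 to 8.28 in the 4 libraries and 7.58 to 7.82 in KO. It was 8.68 in CD41pos WT 3 and 7.71 in CD41neg WT 3. Over oxidative phosphorylation genes it was 6.35 to 6.85 in the 4 and 6.17 to 6.35 in KO, with 7.15 and 6.33 in WT 3. The first 2 results thus lean on CD41pos WT 3 and do not set the 4 below the KO libraries. Mast cell, basophil and eosinophil markers (0.00116, and 0.368) were higher. The labels name no batch. A difference in handling cannot be told apart from a biological difference between the mice behind these libraries, which need not be 1 mouse each. RNA quality and library complexity stay open and untested.

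Of 18 endothelial and stromal markers 8 fell in CD41pos KO and 11 in CD41neg KO (adjusted p = 0.00597 and 6.78e-08, and adjusted p = 0.486 and 0.22 with an estimated correlation), and carried-over RNA of the marrow niche is a candidate source, which the sort for stem cells would be meant to remove. If RNA from 1 kind of stromal cell in varying amounts were the source of all called members, their ratios would stay steady. Across the 6 WT libraries the ratio between pairs of called members ranged over a median of 19.0-fold (12 members, 66 pairs). Among 6 members of at least 10 CPM it ranged over 14.3-fold, and the ratio of Col1a1 to Cxcl12 ran from 0.0165 to 3.92. The list mixes endothelial and stromal markers and the libraries span both gates, so steady ratios were unlikely from the start. The ratios thus show only that the called members did not vary together, and decide nothing about the source. In CD41neg cells the split of the 4 WT libraries is argued against as the only source. There 8 of 11 lower members remained past the threshold with its term, a fit that leans on CD41neg WT 3 and the shared shift. Their median was -3.77 (quartiles -4.28 and -3.42) without the term and -3.56 (-4.39 and -2.67) with it. Over all 18 members it was -3.42 (-4.06 and -1.73), then -2.67 (-3.90 and -1.23). In CD41pos cells 4 of 8 remained, and the folds of the 8 became smaller (median -3.44, quartiles -4.75 and -2.65, then -2.61, -3.31 and -2.36). Their median SE was 0.71, then 0.77. The camera call for the list ended there (0.0535, with 3 members higher and a list median of -2.29 against -1.81). Lost calls alone do not speak for the split. It overlaps the genotype in the same way in both gates, since the WT arm holds some of the 4 libraries and the KO arm none. In both gates all WT libraries are numbered before all KO libraries, so a batch that follows library number cannot be told apart from the genotype. RNA from 1 or several kinds of stromal cell, such a batch and an effect of the genotype stay open.

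The Runx1 gene total was higher in KO in both gates. Normalization is argued against, since the smallest log2 fold change over both gates and 4 other scalings or units was 1.03. The split of the 4 WT libraries is argued against as the only source, since the smaller change with their term was 0.98. A batch that follows library number cannot be told apart from the genotype, since the WT libraries are numbered 1 to 10 and the KO libraries 13 to 22. An effect of the genotype, such as more reads from a transcript that remains after recombination, may account for it and was not tested.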

How the results depend on the processing

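Alternatives with the 4 WT libraries numbered up to 6 or with Y-linked level as a covariate were chosen after seeing the data. The same holds for the fit of KO libraries alone and for list tests with the animal label as a fixed block. The cause was not tested unless stated. Of 279 called results for named genes, 110 kept direction and call in every alternative planned before the data were examined, and 0 reversed. The count for KO against WT in CD41pos cells (3309) became 2154 with only the groups compared, 957 with the replicate number as a block, 6456 with quality weights, 2090 on log2(TPM + 0.1), 1417 with a minimum log2 change of 1 and 7469 without the 4 WT libraries, and 965 to 4076 leaving out 1 library. In CD41neg cells (1517) it became 2989 with DESeq2, 458 with the block, 3395 with quality weights, 827 with the minimum change and 341 to 3856 leaving out 1 library. For the gates of WT (1084) it became 2301 with DESeq2, 201 with only the groups compared, 42 with the block, 582 with the minimum change, 4672 without the 4 libraries, 258 with only these, and 442 to 1166 leaving out 1. For the gates of KO (541) it became 1242 with DESeq2, 1505 with only the groups compared, 156 with the block, 3858 with quality weights, 1464 without the 4 libraries, 2222 with the block in KO libraries alone, and 196 to 1041 leaving out 1. The interaction (0) gave 67 with DESeq2, 2 with no low-count filter, 1 with the block, 3 with quality weights, 7 on log2(TPM + 1), 26 on log2(TPM + 0.1), 3368 without the 4 libraries and 0 to 2 leaving out 1; without the 4 libraries a lone WT library per gate is assumed to vary like the other groups. Of the 130 list tests 47 passed, 1 with an estimated correlation, 22 with fry and 46 to 54 leaving out 1 library. For the block, numbers paired the KO gates, whereas WT and KO libraries of 1 number share only a number. CD41pos WT 4 and CD41neg WT 4, joined by the label block, correlated at -0.52 and held 22.5 and 0 CPM of Ddx3y. The 42 therefore cannot show what pairing does in WT. With WT paired by library number, also planned, 1046 genes passed for the gates of WT, 607 for those of KO and 0 for the interaction. Those WT pairs correlated at -0.22, 0.59 and 0.03. Reversals were in results that had not passed, save for lists. Runx2 in CD41pos cells turned to 0.011, 0.0742 and 0.114 with quality weights, log2(TPM + 1) and log2(TPM + 0.1), and between the KO gates to 0.011, 0.0218 and 0.0108 with the fixed, random and library-number blocks and 0.0559 with the Y-linked covariate, with -0.36 to 0.15 leaving out 1 library. In the interaction, leaving out 1 library gave Runx1 -0.0336 to 0.22 and Runx3 -0.189 to 0.0219, quality weights gave Runx3 0.00974, and Itga2b was 0.28 without the 4 libraries. Adjusted p-values of lists that turned were 7.28e-09 to 0.356 (ribosomal proteins, WT gates) and 4.69e-13 to 0.114 (interaction) leaving out 1 library, 0.131 (immediate early genes, CD41pos, term for the 4 libraries) and 0.534 (neutrophil markers, interaction, block). Of 300 named results, 271 held with the term for the 4 libraries, 25 lost and 4 gained a call. With the Y-linked covariate 25 lost it. That covariate kept 10 of 11 list calls of KO against WT in CD41neg cells, 7 of 8 of the interaction and all of the other comparisons. Calls lost with it are not marked beside the results above. In the splits of 3 against 3 the 10 possible are too few for a share under 0.05. The real counts and highest others were 3309 and 0, 1517 and 1, 1084 and 8, and 541 and 0 (1 split of each as large). For the interaction 30 of 30 drawn splits gave as many as the real 0, the highest other being 0. With a real count of 0 every split must do so, and that share decides nothing. Totals overlapped between the genotypes in CD41pos and between the gates in KO, but each CD41neg KO library exceeded each CD41neg WT library (50342270 against 50239678 at the closest), and a gene under about 0.1 CPM rests on few counts.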

Other observations

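The genes in this part were chosen after their values were seen, and no explanation was tested.

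Jchain, which joins IgA and IgM, ran from 79.3 to 2822 CPM over the 6 WT libraries and from 10.1 to 95.1 CPM over the 6 KO libraries, and was highest in CD41neg WT 2 (2822 CPM) and CD41neg WT 4 (2346 CPM). In those 2 libraries Mzb1 was 128 and 94.1 CPM, against 6.83 CPM in CD41neg WT 3, and Derl3 57.3 and 35.6 against 4.81 CPM. Both libraries belong to the 4 WT libraries that stand apart, but the other 2 of these, CD41pos WT 1 and 4, held 16.1 and 13.5 CPM of Mzb1. CD41neg KO 1 held 13.0 CPM of Mzb1, above the 6.36 and 6.83 CPM of both WT 3 libraries, and Pou2af1 was 14.7, 5.11 and 7.57 CPM in CD41neg KO against 4.82, 3.16 and 2.12 CPM in CD41pos WT.

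Some genes were near absent in 8 libraries and present in the 4 WT libraries numbered up to 6: BC018473 at 42.6 to 63.4 against 0 to 0.671 CPM, Gm42226 at 26.4 to 46.3 against 0.0527 to 0.341 CPM, and St6galnac2, a sialyltransferase gene, at 11.4 to 20.6 against 0.292 to 1.36 CPM.

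The labels put WT 4 in both gates, yet Ddx3y was 22.5 CPM in CD41pos WT 4 and 0 in CD41neg WT 4, whose library number follows that of CD41pos WT 1 (0.0355 CPM). CD41pos WT 4 and CD41neg WT 2, numbered 5 and 6, held 22.5 and 19.4 CPM, and their deviations from the group means correlated at 0.59. The other WT pairs by library number correlated at -0.22 (CD41pos WT 1 with CD41neg WT 4) and 0.03 (WT 3 of each gate), so the pairing of WT libraries stays unsettled. WT libraries with Ddx3y held Xist as well, while KO 1 (97.4 and 103 CPM) and KO 3 (83.4 and 92.9 CPM) had Ddx3y with about 1 CPM of Xist, and KO 2 had Xist (318 and 308 CPM) with 0.161 and 0.155 CPM of Ddx3y, each pair giving CD41pos first.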
